A study of Homo sapiens with 12 samples.

How the data were processed

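Total RNA of MCF7 cells was prepared with a TruSeq total RNA kit and sequenced in pairs of 76 bases on an Illumina HiSeq, per the labels' protocols. The series text gives stimulation times of 0, 60 and 120 min, reads of 101 bases and a mouse genome, while the sample labels give 0, 45 and 90 min, 76 bases and hg19; the sample labels were used. The authors aligned reads with TopHat2 to hg19 and used Cuffdiff, per the submitters' processing notes, with versions not given in the sources used here. The authors deposited FPKM values per gene, which are fragments scaled by transcript length and by mapped fragments, together with the number of alignments per library, 108170000 to 124328000. Further library scaling by the authors is not given in the sources used here. An FPKM of exactly 0 is reported only as listed at 0, since it can be a failed estimate. The deposited tables of differing genes hold a score, the z-score of linear FPKM per gene over the 12 libraries. In them the replicate numbers were exchanged against the expression table in 10 of 18 group and table pairs, so they were used only at group level. Among the rows of expression values, 25 names had been turned into dates and were not named.

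Samples were grouped by line and time from their titles, 2 libraries in each of 6 groups. The model, contrasts, gene lists and naming rule were fixed before the data were examined; the library axis and the tests of the slope, of blood cell genes and of the share of the line differences kept were not. As the values were FPKM, log2(FPKM + 1) was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend), with 1 mean per group, all 12 libraries and 6 residual degrees of freedom, for genes with at least 1 FPKM in at least 2 libraries. All tests were two-sided, with Benjamini-Hochberg adjustment within a comparison and a threshold of 0.05. There were 9 contrasts: the lines at each time, TNFα in each line at each time, and the difference of response at each time. A further model compared the lines over all times with time as a term. Because only 2 libraries make up a group, the spread is estimated jointly over the groups, and precision is limited by their number; no alternative at equal depth was run.

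Fixed gene lists, 22 in number, were tested with camera at a correlation of 0.01, and 20 of them had members past the filter. Fibroblast and blood cell markers had 0, and the list of 28 cytokines and chemokines had only 5. P values were adjusted over 200 list and comparison pairs, of which 51 passed; 10 passed with an estimated correlation, and 92 with fry, which asks whether a list's genes move on balance one way and compares them with no other genes. Older symbols were matched through RefSeq names of assembly GRCh38.p14, used for names only. The slope of one line's changes on the other's was given a 95% interval from 2000 resamples of genes. It was fitted through the origin over list members called as risen in either line, so the largest changes weigh most. Named genes followed a fixed rule: the 8 largest rises and falls among called genes (6 for TNFα and response differences) with at least 2 FPKM in the higher group and replicate ranges apart, short RNAs left out; up to 4 members per described list; and IL6, CXCL8, CCL2, NFKBIA, TNFAIP3, ICAM1 and PPM1D in TNFα comparisons. The library axis is the first principal axis of the deviations of libraries from their group means, which held 49.95% of that variance. GC content and length were taken from the longest transcript per gene of GENCODE release 29, found for 97.9% of the tested genes.

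The fits were tested on simulated data drawn from the real means and spreads of 10572 genes. Errors were drawn independently for each gene and library, so the library axis and the GC trend of the real data were left out. The shares and false calls below therefore hold for independent errors only. For the lines at 0 min 82.1% of genes changed by 0.5, 98.5% of those changed by 1 and 100% of those changed by 2 on the log2 scale were recovered, with 10 false calls. For the response difference at 90 min the shares were 50.7%, 95.5% and 98.5%, also with 10 false calls. Alternatives were other pseudocounts, filters, scalings, eBayes without trend, only the groups compared, a replicate block and leaving out each library; a covariate for the library axis and sets without doubted libraries were chosen after seeing the data.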

Results

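MCF7 cells, an estrogen receptor positive human breast cancer line, were profiled by total RNA sequencing in an unedited form (NAIL-WT) and after CRISPR/Cas9 editing of 2 NFκB binding sites in the promoter of the long non-coding RNA gene NAIL (NAIL-ΔNFκB). Both lines received tumour necrosis factor alpha (TNFα), an inflammatory cytokine that activates the transcription factor NFκB, at 10 ng/ml for 0, 45 or 90 min. Each of the 6 groups had 2 libraries, 12 in all, with 108170000 to 124328000 alignments per library. The values were FPKM, and 10572 of 20213 gene rows reached 1 FPKM in at least 2 libraries and were tested. Replicates correlated across these genes with r between 0.994 and 0.998 on the log2 scale. The labels name no separate cultures or clones, so the p-values measure the spread between these libraries, which may be technical. The edited gene itself, LOC105375914, was not analysed here, so the effect of the edit on its transcript is not reported. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and are given with the standard error of the limma fit; levels are means ± SD with n = 2 unless another n is given.

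The first question was how the edited line differed from NAIL-WT before stimulation. At 0 min the imprinted non-coding RNA H19 was far higher in the edited line, at 131 ± 9.96 FPKM against 14.8 ± 2.43 FPKM in NAIL-WT, a log2 difference of 3.07 ± 0.11. PLCXD3 was higher by 1.66 ± 0.06, the monocarboxylate transporter SLC16A7 by 1.51 ± 0.06, the heparan sulfatase SULF1 by 1.37 ± 0.09, the non-coding RNA PURPL by 1.35 ± 0.09, the WNT antagonist DKK1 by 1.19 ± 0.10, LOC105369486 by 1.18 ± 0.11 and SNX7 by 1.13 ± 0.12. The fatty acid receptor CD36 was at 0.907 ± 0.0288 FPKM in the edited line and 11.8 ± 0.882 FPKM in NAIL-WT, a log2 difference of -2.75 ± 0.08. The 2 subunits of calprotectin were also lower, S100A9 with a log2 difference of -2.69 ± 0.11 and S100A8 with -1.96 ± 0.09. Both epithelial ETS factors named by the rule were lower: EHF differed by -2.68 ± 0.10 and ELF5, at 36.5 ± 3.26 FPKM in NAIL-WT and 6.08 ± 0.221 FPKM in the edited line, by -2.40 ± 0.08. ANKRD30A differed by -2.29 ± 0.07 and the growth factor binding protein IGFBP5 by -1.80 ± 0.06. The histone gene HIST1H4F differed by -4.16 ± 0.17, but it has near-identical copies, so its value is uncertain.

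**Figure D1:**
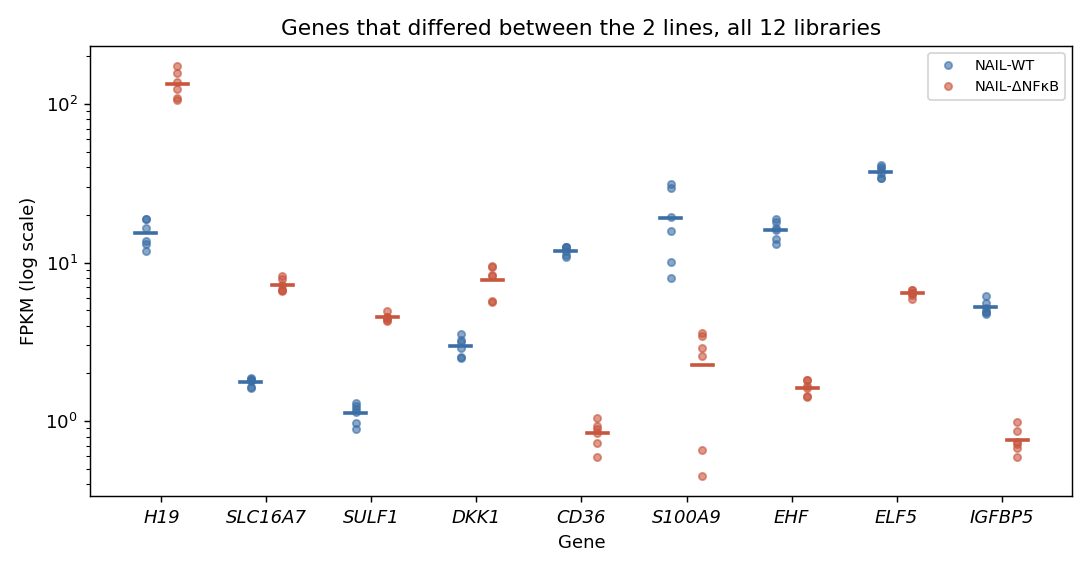
FPKM on a log axis of 9 genes in the 12 libraries. Points are single libraries of all 3 times, 6 per line, and bars are means over the 6; H19 lies higher and CD36, EHF and ELF5 lie lower in every library of the edited line than in any NAIL-WT library.

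Of the fixed gene lists at 0 min, cholesterol synthesis and the unfolded protein and integrated stress response had some members lower in the edited line and passed camera, but neither list passed with an estimated correlation. In the stress response list 9 of 19 measured members were lower and 0 higher, and 9 lower and 1 higher when adjusted over the list alone. Its examples were ATF4, the transcription factor of the integrated stress response, at -0.49 ± 0.10, SEL1L at -0.42 ± 0.09, CRELD2 at -0.40 ± 0.06 and CHAC1, a glutathione-degrading enzyme, at -0.39 ± 0.07. In the cholesterol list 3 of 17 were lower, both over all genes and adjusted over the list alone. These were SREBF2, the master regulator of sterol synthesis, at -0.48 ± 0.07, STARD4 at -0.44 ± 0.06 and CYP51A1 at -0.34 ± 0.06. The camera adjusted p was 0.0028 for the stress response and 0.00486 for cholesterol synthesis; with an estimated correlation the adjusted p was 0.223 and 0.123. ATF4 and SEL1L did not pass without NAIL-ΔNFκB 0 min replicate 2 (-0.48 and -0.39) or without NAIL-WT 0 min replicate 2 (-0.39 and -0.31). In all, 1261 genes passed the limma test at 0 min, 487 higher and 774 lower in the edited line. The count was 704 without NAIL-ΔNFκB 0 min replicate 1, 817 without replicate 2 of that group, 603 with a minimum of 5 FPKM and 2522 with a covariate, chosen after seeing the data, for the main axis of spread between replicate libraries.

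At 45 min of TNFα H19 again led the genes that were higher in the edited line. It differed by 2.98 ± 0.11, PLCXD3 by 1.83 ± 0.06, SLC16A7 by 1.72 ± 0.06, SULF1 by 1.41 ± 0.09, DKK1 by 1.41 ± 0.10, the fatty acid transporter SLC27A6 by 1.35 ± 0.07, ADAMTS19 by 1.28 ± 0.06 and SNX7 by 1.28 ± 0.12. Lower genes were CD36 at -2.71 ± 0.08, EHF at -2.58 ± 0.10, S100A9 at -2.31 ± 0.11, ELF5 at -2.27 ± 0.08, ANKRD30A at -2.27 ± 0.07, IGFBP5 at -1.83 ± 0.06 and AK7 at -1.66 ± 0.07, besides the uncertain HIST1H4F at -4.01 ± 0.17. Of 17 luminal epithelial markers 7 were lower and 1 higher (8 lower and 2 higher adjusted over the list alone), among them SPDEF at -0.71 ± 0.07, ESRP1 at -0.46 ± 0.09 and the epithelial cadherin CDH1 at -0.43 ± 0.09. The camera adjusted p was 0.0245, and with an estimated correlation the adjusted p was 0.253. Of 24 NFκB targets 5 were lower and 1 higher, also adjusted over the list alone (adjusted p 0.0482, and 0.468 with an estimated correlation), and of 5 cytokines 3 were lower and 1 higher, also adjusted over the list alone (adjusted p 0.0389, and 0.26 with an estimated correlation). In the stress response list 9 of 19 members were lower and 2 higher (10 and 2 adjusted over the list alone), led by CHAC1 at -0.65 ± 0.07 and the pseudokinase TRIB3 at -0.56 ± 0.06, with adjusted p 0.00783, and adjusted p 0.26 with an estimated correlation. Of 17 cholesterol synthesis genes 9 were lower and 2 higher, also adjusted over the list alone. That list did not pass camera at 45 min (adjusted p 0.0547, and 0.223 with an estimated correlation). Of 40 ribosomal protein genes 21 were higher and 0 lower (22 adjusted over the list alone), such as RPS27A at 0.64 ± 0.09 and RPS5 at 0.59 ± 0.12. The adjusted p was 0.000243, and 0.841 with an estimated correlation. The luminal, NFκB and ribosomal lists did not pass camera between the lines at 0 min (adjusted p 0.206, 0.887 and 0.925). They did not pass at 90 min either (adjusted p 0.577, 0.574 and 0.948). On the main axis of spread between replicates the edited-line libraries of 45 min had the highest scores, 9.29 and 9.98, and NAIL-WT replicate 1 of 45 and of 0 min the lowest, -12.0 and -10.2, while the other 8 libraries ranged from -6.38 to 6.40. Across genes the difference between the lines at 45 min followed the GC content of the transcript, with Spearman's rho = -0.487 over 10349 genes, which are not independent replicates, and rho = -0.291 with the axis as a covariate. Without the covariate rho was 0.008 at 0 min and 0.059 at 90 min. In all, 3695 genes passed, 2270 higher and 1425 lower. The split turned to 1543 higher and 1669 lower with the library axis as a covariate, and it was 906 and 836 without NAIL-WT 45 min replicate 1. The count was 1711 and 2078 without NAIL-ΔNFκB 45 min replicate 1 or 2, 1742 without NAIL-WT 45 min replicate 1, and 2385 with a minimum of 5 FPKM.

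At 90 min 1603 genes passed, 461 higher and 1142 lower in the edited line, and the stress gene DDIT4 joined those that led at the earlier times. DDIT4, an inhibitor of mTOR signalling, was at 6.04 ± 0.0224 FPKM in the edited line and 28.7 ± 1.52 FPKM in NAIL-WT, a log2 difference of -2.08 ± 0.10. CHAC1 was at 2.12 ± 0.112 FPKM against 7.94 ± 0.552 FPKM, a difference of -1.52 ± 0.07. Higher genes were H19 at 3.07 ± 0.11, PLCXD3 at 1.57 ± 0.06, SLC16A7 at 1.49 ± 0.06, SULF1 at 1.36 ± 0.09, LOC105369486 at 1.19 ± 0.11, C6orf141 at 1.18 ± 0.11, SLC27A6 at 1.17 ± 0.07 and SNX7 at 1.12 ± 0.12. Lower genes were CD36 at -2.99 ± 0.08, EHF at -2.83 ± 0.10, S100A9 at -2.80 ± 0.11, ELF5 at -2.45 ± 0.08, ANKRD30A at -2.18 ± 0.07 and IGFBP5 at -1.83 ± 0.06, besides the uncertain HIST1H4F at -4.29 ± 0.17. In the stress response list 11 of 19 members were lower and 1 higher (12 and 1 adjusted over the list alone), with ATF4 at -0.65 ± 0.10, TRIB3 at -0.59 ± 0.06 and the cystine transporter SLC7A11 at -0.53 ± 0.06. Of 17 cholesterol synthesis genes 7 were lower and 0 higher (9 adjusted over the list alone), with SREBF2 at -0.56 ± 0.07 and STARD4 at -0.49 ± 0.06. Of the 28 listed cytokines only 5 passed the filter, and of these 4 were lower and 1 higher, counts that were the same adjusted over the list alone. The chemokine CCL20 was at 1.92 ± 0.00272 FPKM in the edited line and 7.10 ± 0.450 FPKM in NAIL-WT, and the vasoconstrictor EDN1 differed by -0.77 ± 0.07, TNF by -0.52 ± 0.06 and the EGF family ligand AREG by 0.35 ± 0.08. AREG did not pass without NAIL-ΔNFκB 90 min replicate 1 (0.30) or NAIL-WT 90 min replicate 2 (0.30). By camera the adjusted p was 0.00029 for the stress response, 0.00215 for cholesterol synthesis and 0.00338 for cytokines. With an estimated correlation the adjusted p was 0.152, 0.0924 and 0.152. Under quantile normalization the split of calls was 706 higher and 1015 lower. The count was 787 and 905 without NAIL-WT 90 min replicate 1 or 2, 962 and 789 without NAIL-ΔNFκB 90 min replicate 1 or 2, 805 with a minimum of 5 FPKM, 2774 when only the groups compared were fitted, 2602 with the library axis as a covariate and 2469 without the second NAIL-WT libraries of 0 and 45 min.

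Over the 3 times 253 genes were higher in the edited line at each time and 559 were lower at each time. With time as a term and 6 libraries per line, 3331 genes passed, 1491 higher and 1840 lower. H19 led the higher genes at 3.04 ± 0.06, and DOCK10, a guanine nucleotide exchange factor, differed by 1.25 ± 0.03. ANKRD30A at -2.25 ± 0.04, IGFBP5 at -1.82 ± 0.03 and AK7 at -1.73 ± 0.04 were among the lower genes. The stress response list had 9 of 19 members lower and 2 higher (10 and 2 adjusted over the list alone; camera adjusted p 0.00256, adjusted p 0.249 with an estimated correlation). The cholesterol list had 6 of 17 lower and 1 higher (8 and 1 adjusted over the list alone; adjusted p 0.004, adjusted p 0.136 with an estimated correlation). The split turned to 2037 higher and 1919 lower under quantile normalization and to 1807 and 1754 under median scaling. The count was 1742 with a minimum of 5 FPKM and 5340 with the library axis as a covariate.

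The next question was how each line responded to TNFα. In NAIL-WT at 45 min NFKBIA, the inhibitor of NFκB, was at 307 ± 2.24 FPKM against 28.2 ± 0.123 FPKM at 0 min, a log2 rise of 3.40 ± 0.08. The ephrin ligand EFNA1 rose by 3.81 ± 0.09, the NFκB feedback deubiquitinase TNFAIP3 by 3.21 ± 0.08, the adhesion molecule ICAM1 by 3.12 ± 0.08 and the transcription factor IRF1 by 2.53 ± 0.06. CCL20 was listed at 0 in both libraries at 0 min and was at 3.59 ± 0.239 FPKM at 45 min, so no fold is given. The Notch target HES1 had a log2 change of -0.79 ± 0.07, ID1 of -0.77 ± 0.12, GADD45G of -0.67 ± 0.08, FOS of -0.56 ± 0.09, MIR181A1HG of -0.56 ± 0.10 and TXNIP of -0.56 ± 0.08. MIR181A1HG did not pass without NAIL-WT 0 min replicate 1 (-0.56) or 2 (-0.56) or NAIL-WT 45 min replicate 1 (-0.46), or without a filter. Without a filter ID1 did not pass either, and TXNIP did not pass when only the groups compared were fitted. Of 24 measured NFκB targets 20 rose and 0 fell (22 and 0 adjusted over the list alone), with a median of 1.24. Of 22 immediate early genes 12 rose and 2 fell (14 and 2 adjusted over the list alone), with NR4A1 at 2.04 ± 0.08, EGR1 at 2.00 ± 0.07 and JUNB at 1.81 ± 0.10. Of 5 cytokines 4 rose (5 adjusted over the list alone), with AREG at 0.72 ± 0.08 and CSF1 at 0.57 ± 0.06. The camera adjusted p was 5.34e-94, 1.92e-39 and 1.72e-20, and with an estimated correlation the adjusted p was 0.00161, 0.00512 and 0.00512. Of 21 p53 targets 5 rose and 1 fell (7 and 1 adjusted over the list alone), with adjusted p 4.84e-05, and adjusted p 0.0462 with an estimated correlation. PPM1D, a phosphatase that acts on p38, changed by less than its error at 0.02 ± 0.07. In all, 209 genes passed, 178 higher and 31 lower; the count was 107 with a minimum of 5 FPKM, 110 when only the groups compared were fitted, and 384 with the library axis as a covariate.

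In the edited line at 45 min 5 of the 6 leading genes were among the 6 that led in NAIL-WT. EFNA1 rose by 3.88 ± 0.09, NFKBIA by 3.49 ± 0.08, TNFAIP3 by 3.41 ± 0.08, ICAM1 by 2.83 ± 0.08, IRF1 by 2.43 ± 0.06 and EGR1 by 1.88 ± 0.07. CCL20 was listed at 0 in both libraries at 0 min and was at 1.59 ± 0.0842 FPKM. The changes of ID1, HES1, FOS, CITED2, VASN and EPHB3 were -0.92 ± 0.12, -0.79 ± 0.07, -0.74 ± 0.09, -0.71 ± 0.08, -0.70 ± 0.12 and -0.64 ± 0.11. VASN and EPHB3 did not pass without NAIL-ΔNFκB 45 min replicate 1 (-0.66 and -0.52). Of 24 NFκB targets 20 rose and 0 fell, also adjusted over the list alone, with a median of 1.03. Of 22 immediate early genes 13 rose and 3 fell, also adjusted over the list alone, with ZFP36 at 1.82 ± 0.09 and JUNB at 1.76 ± 0.10. Of 5 cytokines 4 rose (5 adjusted over the list alone), with AREG at 0.86 ± 0.08. For these lists the camera adjusted p was 1.09e-23, 2.82e-09 and 0.000123, and with an estimated correlation the adjusted p was 0.0145, 0.0766 and 0.0867. Of 21 p53 targets 8 rose and 0 fell (8 and 1 adjusted over the list alone), but the list did not pass (adjusted p 0.066, and 0.24 with an estimated correlation). PPM1D was at 0.06 ± 0.07 and did not pass. The 2661 genes that passed were 1447 higher and 1214 lower. Fewer genes passed when either NAIL-ΔNFκB library of 45 min or of 0 min was left out. The same held for either NAIL-WT library of 90 min, a group that is not compared here. This count thus depended on the libraries fitted but was not shown to rest on any single one. It was 746 with the library axis as a covariate, 1176 without a filter, 1752 with a minimum of 5 FPKM, and 4589 without the second NAIL-WT libraries of 0 and 45 min. The change across genes followed GC content with rho = -0.631. Of the genes that rose in NAIL-WT 155 also rose in the edited line, where independent lists of these sizes would share 24.4.

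At 90 min in NAIL-WT EFNA1 rose by 4.16 ± 0.09, ICAM1 by 4.07 ± 0.08, TNFAIP3 by 3.60 ± 0.08, NFKBIA by 3.50 ± 0.08 and the NFκB subunit RELB by 2.92 ± 0.07. CCL20 was at 7.10 ± 0.450 FPKM. HES1 fell by 1.70 on the log2 scale, FOS fell by 1.44, PRR15L fell by 1.21, TENT5C fell by 1.02, ID1 fell by 1.01 and the receptor kinase EPHB3 fell by 0.79, with errors of 0.07 to 0.12. Of 24 NFκB targets 23 rose and 0 fell, also adjusted over the list alone, with a median of 1.56. Of 22 immediate early genes 16 rose and 2 fell (16 and 3 adjusted over the list alone), with MAFF at 1.87 ± 0.07. Of 5 cytokines 4 rose, also adjusted over the list alone, with AREG at 1.35 ± 0.08 and CSF1 at 1.06 ± 0.06. Of 21 p53 targets 10 rose and 2 fell (12 and 2 adjusted over the list alone), with the stress cytokine GDF15 at 1.72 ± 0.12 and the cell cycle inhibitor CDKN1A at 1.48 ± 0.07. Of 23 TNF receptor signalling genes 11 rose and 0 fell (13 and 0 adjusted over the list alone), with the kinase IKBKE at 1.35 ± 0.07 and TRAF3 at 0.82 ± 0.08. The camera adjusted p was 1.18e-36, 3.46e-05, 3.15e-07, 0.00135 and 0.0206 for these lists in turn. With an estimated correlation the adjusted p was 0.00512, 0.152, 0.0427, 0.0867 and 0.152. PPM1D was at 0.15 ± 0.07 and did not pass, but it passed at 0.18 with the library axis as a covariate, and it turned to -0.041 under quantile normalization. In all, 2267 genes passed, 2057 higher and 210 lower, but the median of all genes was itself shifted by 0.12. Under median scaling, which removes this shift, 647 were higher and 669 lower, and under quantile normalization 652 were higher and 551 lower. The count was 834 and 1055 without NAIL-WT 90 min replicate 1 or 2, 3919 with the library axis as a covariate, and 4002 without the second NAIL-WT libraries of 0 and 45 min.

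At 90 min in the edited line ICAM1 rose by 3.84 ± 0.08, EFNA1 by 3.84 ± 0.09, TNFAIP3 by 3.83 ± 0.08, NFKBIA by 3.57 ± 0.08, RELB by 2.95 ± 0.07 and the sugar transporter SLC2A6 by 2.70 ± 0.09. CCL20 was at 1.92 ± 0.00272 FPKM. HES1 fell by 1.57, FOS fell by 1.42, PRR15L fell by 1.24, TENT5C fell by 1.07, RBBP8NL fell by 0.92 and ID1 fell by 0.91 on the log2 scale. Of 24 NFκB targets 23 rose and 0 fell, also adjusted over the list alone, with a median of 1.40. Of 22 immediate early genes 15 rose and 2 fell (17 and 2 adjusted over the list alone), with MAFF at 1.83 ± 0.07. Of 5 cytokines 4 rose, also adjusted over the list alone, with AREG at 1.32 ± 0.08. Of 21 p53 targets 8 rose and 2 fell (10 and 2 adjusted over the list alone), with CDKN1A at 1.55 ± 0.07. Of 23 TNF receptor signalling genes 9 rose and 1 fell (12 and 1 adjusted over the list alone), with TRAF3 at 0.81 ± 0.08. In turn, the camera adjusted p was 2.05e-40, 5.84e-09, 4.2e-05, 0.0188 and 0.0159. With an estimated correlation the adjusted p was 0.00512, 0.0766, 0.0766, 0.152 and 0.152. PPM1D was at 0.16 ± 0.07 and did not pass, but it passed at 0.17 with the library axis as a covariate, and it was at 0.022 under quantile normalization. In all, 1554 genes passed, 1322 higher and 232 lower. Under median scaling 585 were higher and 679 lower, and under quantile normalization 670 were higher and 550 lower. The count was 585 and 716 without NAIL-ΔNFκB 90 min replicate 1 or 2, 835 and 747 without NAIL-ΔNFκB 0 min replicate 1 or 2, 929 with a minimum of 5 FPKM, 3179 with the library axis as a covariate, and 2636 without the second NAIL-WT libraries of 0 and 45 min. Of the genes that rose in NAIL-WT 1144 also rose in the edited line, where independent lists would share 257. The shift of all genes, 0.117 in NAIL-WT and 0.078 in the edited line, enters both lists, so independence is no fair expectation. Under median scaling 647 genes rose in NAIL-WT, so 1144 is no count of genes induced by TNFα in both lines.

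**Figure D2:**
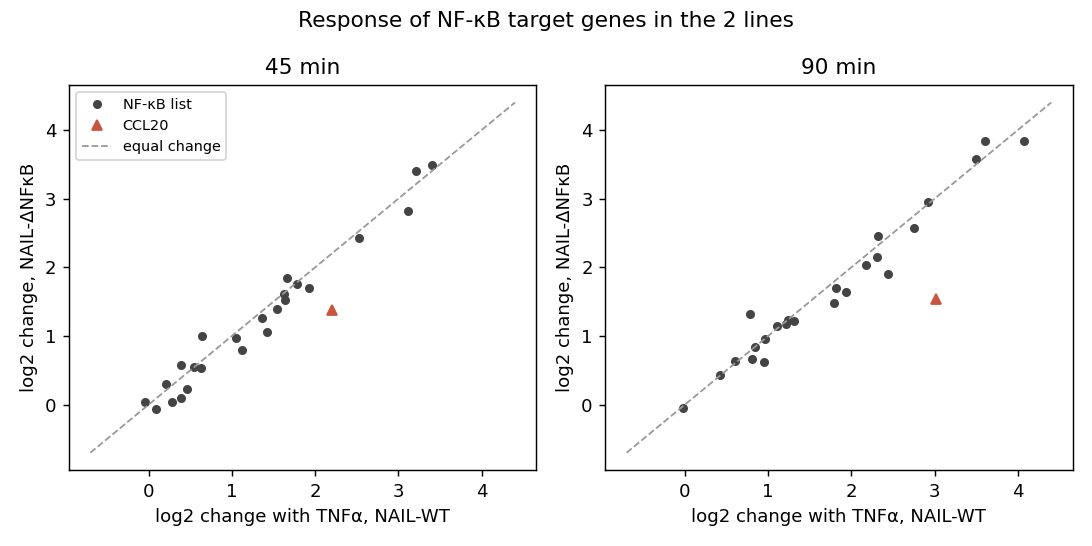
Log2 change with TNFα of the 24 measured genes of the NFκB list (points) and of CCL20 (triangle) in NAIL-WT (x axis) and NAIL-ΔNFκB (y axis), at 45 and 90 min; the dashed line marks equal change. The list lies near the line, with slopes of 0.969 and 0.966 over the 21 and 23 members called as risen in either line. CCL20 lies below the line, and its values start from a listed 0 and depend on the pseudocount of 1.

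The question central to the design was whether the response to TNFα differed between the lines, tested as the interaction of line and time. For the NFκB targets as a group the slope of the edited line's changes on those of NAIL-WT was 0.969 (95% interval 0.913 to 1.01 over genes) at 45 min and 0.966 (0.918 to 1.01) at 90 min. These slopes cover the 21 and 23 members called as risen in either line. The median difference over the 24 members was -0.09 at 45 min and -0.03 at 90 min, with a larger rise in NAIL-WT for 16 and 15 of them. Over all 102 genes that rose by over 1 on the log2 scale in either line by 90 min 75 rose more in NAIL-WT, with a median difference of -0.142, while the median of all tested genes was -0.041. At 45 min 27 of 50 such genes rose more in NAIL-WT, with a median difference of -0.021. The differences of NFKBIA, TNFAIP3 and ICAM1 at 90 min were 0.07 ± 0.11, 0.23 ± 0.11 and -0.23 ± 0.12, and none passed. At 45 min the same genes were at 0.09 ± 0.11, 0.19 ± 0.11 and -0.29 ± 0.12, and the first 2 turned to -0.13 and -0.02 under quantile normalization. ICAM1 passed at 45 min without NAIL-WT 45 min replicate 2 (-0.40). The NFκB list had a camera adjusted p of 0.0185 at 45 min with 0 members past the test (0 higher and 2 lower adjusted over the list alone), and adjusted p 0.4 with an estimated correlation. It also did not pass with fry (0.109), with the library axis as a covariate (0.0963), without a filter (0.0519) or without NAIL-ΔNFκB 0 min replicate 2 (0.0808). At 90 min the list did not pass, but it passed without NAIL-WT 90 min replicate 2 (0.0383) and without NAIL-ΔNFκB 0 min replicate 1 (0.0443). PPM1D was at 0.04 ± 0.10 at 45 min and 0.01 ± 0.10 at 90 min.

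CCL20 stood apart, with a smaller response in the edited line at both times. The difference was -0.83 ± 0.09 at 45 min (limma adjusted p 0.00791) and -1.47 ± 0.09 at 90 min (adjusted p 1.51e-05). The difference at 45 min did not pass without NAIL-ΔNFκB 0 min replicate 1 or 2 (-0.83 each) or NAIL-ΔNFκB 45 min replicate 1 (-0.79), with a pseudocount of 0.1 (-1.13), without a filter or when only the groups compared were fitted. At 90 min 3 further genes passed, all with a smaller rise in the edited line. DDIT4 went from 9.05 ± 1.56 to 28.7 ± 1.52 FPKM in NAIL-WT and from 4.93 ± 0.106 to 6.04 ± 0.0224 FPKM in the edited line, a difference of -1.32 ± 0.14 (adjusted p 0.00267). CHAC1 went from 1.66 ± 0.159 to 7.94 ± 0.552 FPKM and from 1.02 ± 0.0236 to 2.12 ± 0.112 FPKM, a difference of -1.12 ± 0.10 (adjusted p 0.00104). The cytokine IL17C, which lies below the level set for naming and was chosen after its values were seen, was at 1.73 ± 0.0987 FPKM in NAIL-WT and 0.395 ± 0.0837 FPKM in the edited line at 90 min, with a difference of -0.92 ± 0.12 (adjusted p 0.0225). IL17C passed narrowly: it did not pass without a filter, with a pseudocount of 0.1 (-1.69) or 0.5 (-1.23), or without any 1 of 7 libraries, which were both NAIL-ΔNFκB libraries of 0 min (-0.95 and -0.89) and of 90 min (-0.86 and -0.98), NAIL-WT 0 min replicate 2 (-0.82) and both NAIL-WT libraries of 90 min (-0.96 and -0.88). CCL20, DDIT4 and CHAC1 at 90 min passed in every alternative run. Of the 5 cytokines, 1 was lower at 45 min and 1 at 90 min (2 and 3 adjusted over the list alone), both times CCL20, and TNF was at -0.52 ± 0.08 at 90 min. TNF passed with the library axis as a covariate (-0.52), without a filter (-0.52) and under quantile normalization (-0.49). The list's camera adjusted p was 0.00978 at 45 min and 1.04e-11 at 90 min, and with an estimated correlation the adjusted p was 0.179 and 0.0145. As CCL20 is 1 of its 5 members, the list is not separate evidence from that gene. At 45 min the list also did not pass without NAIL-WT 0 min replicate 1 (0.0649), with a minimum of 5 FPKM (0.0669) or without a filter (0.324). The stress response list had 1 of 19 members lower at 90 min (2 adjusted over the list alone), with adjusted p 0.00272, and adjusted p 0.223 with an estimated correlation. The 40 ribosomal protein genes had a median difference of 0.37 at 45 min with 0 members past the test (1 higher adjusted over the list alone), adjusted p 2.94e-06, and adjusted p 0.717 with an estimated correlation.

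**Figure D3:**
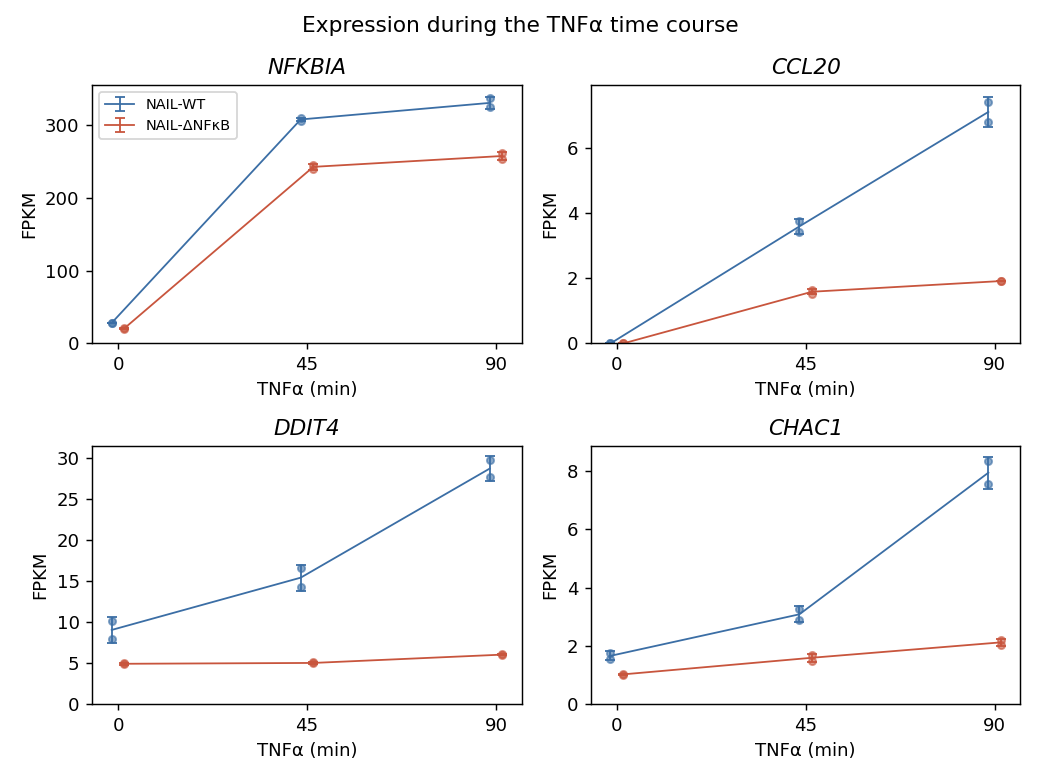
FPKM of NFKBIA, CCL20, DDIT4 and CHAC1 at 0, 45 and 90 min of TNFα in NAIL-WT and NAIL-ΔNFκB. Points are single libraries, lines join the means and bars are the SD of 2 libraries; at 90 min DDIT4 reached 28.7 FPKM in NAIL-WT and 6.04 FPKM in the edited line.

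For the response difference 2032 genes at 45 min and 260 at 90 min had an unadjusted limma p under 0.05. With no difference anywhere a share of 0.05 of the 10572 tested genes would have such a p. The 260 lies below that share. The 2032 lies above it, in a contrast that followed GC content with rho = -0.612. After adjustment 1 gene passed for the response difference at 45 min and 4 at 90 min. The count at 45 min was 0 without NAIL-ΔNFκB 0 min replicate 1 or 2, 0 without NAIL-ΔNFκB 45 min replicate 1, 3 without NAIL-WT 0 min replicate 1, and 958 without NAIL-WT 45 min replicate 2. It was 0 when only the groups compared were fitted and 10 without the second NAIL-WT libraries of 0 and 45 min. At 90 min it was 18 without a filter, 11 under quantile normalization, 11 without those libraries and 12 with the library axis as a covariate. Of cytokines often linked to NFκB, CXCL8 and CCL2 had low values: CXCL8 was at 0.839 ± 0.0554 and 0.910 ± 0.156 FPKM at 90 min in NAIL-WT and the edited line, CCL2 was at 0.262 ± 0.0915 and 0.332 ± 0.0384 FPKM. IL6 was listed at 0 in every NAIL-WT library, which gives no level. None of the 3 passed the filter, so they were not tested.

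The authors' deposited tables of genes that differed between the lines hold 316, 442 and 396 genes at 0, 45 and 90 min, of which 133, 173 and 155 passed the filter here. All of these passed the limma test here with the same sign, a share of 100% (Clopper-Pearson 95% interval from 97.3%, 97.9% and 97.6%). The genes were selected on the same libraries, so this is not independent evidence. In 36, 52 and 50 of the tables' genes no group mean reached 0.1 FPKM.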

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

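The tests of the slope, of blood cell genes and of the share of the line differences kept were chosen only after the results were seen, and the library axis was chosen as a covariate after seeing the data. Results below were picked because the response to TNFα differed between the lines by the test of the difference itself. CCL20 differed by -0.83 at 45 min and -1.47 at 90 min on the log2 scale. At 90 min DDIT4 differed by -1.32, CHAC1 by -1.12 and IL17C by -0.92. Among lists the medians were -0.13 (cytokines, 45 min), -0.094 (NFκB targets, 45 min), 0.37 (ribosomal proteins, 45 min), -0.24 (cytokines, 90 min) and -0.067 (stress response, 90 min). Groups of 2 libraries are too small to test for single outlying libraries.

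The smaller rise of CCL20, DDIT4, CHAC1 and IL17C is more than the NFκB targets as a group showed. The slope at 90 min of the 23 targets called as risen in either line was 0.966. Its lower bound was 0.918, a bound over genes that leaves out the spread between libraries. The 4 genes are not on that list and were picked for their difference, so the slope cannot speak for a weaker response of other genes. The stress response list, which holds CHAC1, had a median of 0.283 in NAIL-WT and 0.143 in the edited line at 90 min, where all genes shifted by 0.117 and 0.078. A small general weakening stays open: of 102 genes that rose by over 1 on the log2 scale in either line by 90 min 75 rose more in NAIL-WT, 33 passed that level in NAIL-WT alone against 7 in the edited line alone, and the median difference was -0.142, with 5% of genes below -0.581, while the median of all tested genes was itself -0.041. At 45 min 27 of 50 such genes rose more in NAIL-WT, 3 passed that level in NAIL-WT alone against 10 in the edited line alone, and the median was -0.021. The NFκB list was lower at 45 min with adjusted p 0.0185, and 0.4 with an estimated correlation. The smaller rise of the 4 genes is not the library axis alone. With the axis as a covariate the differences hardly moved, at -1.46, -1.36, -1.11 and -0.93. All 4 genes stayed past the threshold, but this adds little, as the covariate takes up part of the residual spread. The standard error went from 0.138 to 0.082 for DDIT4, and from 0.122 to 0.124 for IL17C. CCL20, DDIT4 and CHAC1 at 90 min passed in every alternative run, while IL17C, and CCL20 at 45 min, were lost in several. CHAC1 belongs to the stress response list, whose difference at 90 min had adjusted p 0.00272, and 0.223 with an estimated correlation. Whether the edit or another difference between the lines accounts for the smaller rise stays open, because the labels give 1 line per genotype and name no clones.

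More genes passed at 45 min in the edited line than elsewhere, 2661 for TNFα against 209 in NAIL-WT. This ranking depends on the fit: with the axis as a covariate the counts were 746 and 384, fewer than the 3919 for TNFα at 90 min in NAIL-WT, and without NAIL-ΔNFκB 45 min replicate 1 or 2 the 2661 became 221 or 460. Across genes the response difference at 45 min followed transcript GC content with Spearman's rho = -0.612, as GC bias in the libraries would give, and the loadings of the library axis followed it with rho = -0.487. The axis accounts for part of this trend at most: with it as a covariate the rho was -0.375, and for TNFα at 45 min in the edited line it was -0.474 against -0.631 without. With the axis as a covariate 3212 genes passed between the lines at 45 min, 1.25 times the mean of 0 and 90 min in the same fit, which is within the 1.5 times set for the axis as the cause. That ratio came down mostly because the mean of 0 and 90 min rose from 1432 to 2562 while the count at 45 min went from 3695 to 3212, and against the mean without the covariate it was 2.24. The bound did not say which mean was meant, so the axis stays open as a cause. Of genes called only in the edited line 68.7% had the same sign in NAIL-WT, 52.1% of the higher and 86.7% of the lower, which leaves a response shared by both lines open for part of them. The higher genes may mostly reflect the GC trend, and the lower may in part too. TNFα at 45 min in NAIL-WT also followed GC content, with rho = -0.163, and -0.243 with the axis as a covariate. The median of all genes there was -0.030, so these shares do not separate a shared response from the GC trend.

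The differences between the lines at every time were tested by regrouping. Of 100 splits of the 12 libraries 1, the real one, gave as many genes, 3331 against at most 1771 in the others. Every other split mixes the 2 lines, so this shows only that the libraries part by line. It cannot tell whether 2 lines would come to differ this much by chance. With the library axis as a covariate the 3331 genes kept a median share of 0.991 of their log2 difference averaged over times, 0.901 at the 5th percentile. The mean scores of the lines over all times, -0.749 and 0.749, lay close together. At 45 min the scores were -12.0 and 5.15 in NAIL-WT and 9.29 and 9.98 in the edited line, so the share does not speak for that time alone. This test replaced a count of genes still past the threshold, which the smaller residual spread under the covariate nearly fixes. Blood cells as a source of S100A8 and S100A9 in NAIL-WT were not decided by the bounds set, 1% and 10%. The highest marker of the fixed list, CD68, was at 1.97% of the S100A9 level. Blood cells in NAIL-WT alone would raise the markers there. CD68, HBA1 and CD14 were at 0.375, 0.163 and 0.0932 FPKM in NAIL-WT and 0.324, 0.13 and 0.114 FPKM in the edited line. CD68 and HBA1 were thus slightly higher in NAIL-WT and CD14 was lower. The other markers with values were at most 0.012 FPKM in either line. All these values are low and their differences were not tested, so they do not decide whether blood cells were the source. A narrower test on PTPRC, at 0.00247% of the S100A9 level, and LYZ, listed at 0 in NAIL-WT, was picked after the CD68 value was seen and is not counted as a test. The edit itself and clonal divergence of the lines stay open, as the labels give 1 line per genotype.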

How the results depend on the processing

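The library axis, the sets without doubted libraries and the set without the 45 min libraries were chosen after seeing the data. Causes of the changes were not tested, except that a higher minimum tests fewer genes. With the axis as a covariate the counts were 2522 (lines at 0 min), 2602 (90 min), 5340 (all times), 384 and 746 (TNFα 45 min in NAIL-WT and NAIL-ΔNFκB), 3919 and 3179 (90 min) and 12 (response difference at 90 min), the NFκB median of the response difference at 45 min was -0.069 with adjusted p 0.0963, and the response differences of AREG at 45 min and PPM1D at 90 min turned to -0.033 and -0.0090. With a minimum of 5 FPKM the counts were 603, 2385 and 805 for the lines by time, 1742 over all times, 107, 1752 and 929 for TNFα (NAIL-WT 45 min, NAIL-ΔNFκB 45 and 90 min), and the cytokine response difference at 45 min was -0.34 with adjusted p 0.0669. Without a filter they were 1176 (TNFα 45 min, NAIL-ΔNFκB) and 18 (response difference, 90 min), and at 45 min the NFκB and cytokine medians of the response difference were -0.0935 and 0, adjusted p 0.0519 and 0.324. Fitting only the groups compared gave 2774 (lines at 90 min), 110 (TNFα 45 min, NAIL-WT) and 0 (response difference at 45 min). Median scaling gave 1316 and quantile normalization 1203 for TNFα 90 min in NAIL-WT; the latter gave 11 for the response difference at 90 min and turned PPM1D to -0.14 (response difference, 45 min), -0.041 (NAIL-WT, 90 min) and -0.086 (NAIL-ΔNFκB, 45 min), TNFAIP3 to -0.021 and NFKBIA to -0.13 (response difference, 45 min). Without the second NAIL-WT libraries of 0 and 45 min the counts were 2469 (lines at 90 min), 4589, 4002 and 2636 (TNFα 45 min in NAIL-ΔNFκB, 90 min in NAIL-WT and NAIL-ΔNFκB), 10 and 11 (response differences), and PPM1D turned to -0.021 (NAIL-WT, 45 min). Of list and comparison pairs 10 passed with an estimated correlation and 92 with fry, 40 of them shared. With an estimated correlation the adjusted p rose to 0.4 for the NFκB median of -0.094 and 0.179 for the cytokine median of -0.13 (response difference, 45 min), and to 0.0867 and 0.0766 for the cytokine medians of 0.44 and 0.82 in NAIL-ΔNFκB; with fry it was 0.109 for the NFκB median of -0.094.

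Leaving out each library gave 704 to 1451, 1711 to 4498 and 787 to 1824 genes between the lines at 0, 45 and 90 min, 221 to 3499 and 585 to 1848 for TNFα in NAIL-ΔNFκB, 834 to 2711 in NAIL-WT at 90 min, and 0 to 958 and 3 to 6 for the response differences. The NFκB median of the response difference ranged from -0.12 to -0.054 at 45 min and -0.084 to -0.0092 at 90 min, and that of cytokines at 45 min from -0.19 to -0.079. PPM1D ranged from -0.053 to 0.094 for TNFα at 45 min in NAIL-WT, and from -0.037 to 0.11 and -0.066 to 0.081 for the response differences at 45 and 90 min. A lone library is then assumed to vary like the other groups. The replicate block gave 3371 genes between the lines at 45 min, 2205 for TNFα at 45 min in NAIL-ΔNFκB and 1958 at 90 min in NAIL-WT. The numbers as labelled do not pair the libraries over all groups. Only 2 of 15 pairs of groups had correlated deviations over 0.1 (from -0.46 to 0.72). A pairing under exchanged numbers would give negative values, and a block by the labelled numbers does not test it. The 0.72 belongs to NAIL-WT at 0 and 45 min, whose TNFα comparison gave 191 genes with the block and 384 with the axis as a covariate. Values of single genes were compared by their sign and by whether they passed the threshold, not by their size. In the alternatives 2762 kept both, 14 no longer passed, 11 newly passed and 8 changed sign. With each library left out 2892 kept both, 45 no longer passed, 8 newly passed and 7 changed sign. The 2 libraries per group limit every comparison, and no alternative at equal depth was run.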

Other observations

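Of 23 regulators of the p38 and MAPK pathway 8 rose and 1 fell at 90 min of TNFα in NAIL-WT and 8 rose and 0 fell in NAIL-ΔNFκB (9 and 1, and 9 and 0, adjusted over the list alone). MAP3K8, a kinase of the MAPK cascade, rose by 1.78 ± 0.07 and 1.60 ± 0.07, and DUSP16, a MAPK phosphatase, by 1.18 ± 0.07 and 1.19 ± 0.07. The list medians of 0.157 and 0.113 were close to the shifts of all genes, 0.117 and 0.078. The camera adjusted p was 0.0388 and 0.0185, and with an estimated correlation the adjusted p was 0.185 and 0.152. At 90 min the list as a whole thus passed camera only in the preset setting. The estimated correlation was -0.0374, below the 0.01 set, so a larger correlation does not account for the higher p. At 45 min in NAIL-WT 4 members rose and 0 fell (5 and 0 adjusted over the list alone), with adjusted p 6.75e-07, and 0.0228 with an estimated correlation. In NAIL-ΔNFκB at 45 min 5 rose and 2 fell (6 and 3 adjusted over the list alone), and the list did not pass (adjusted p 0.308, and 0.507 with an estimated correlation). Of 11 heat shock genes 3 fell in each line and 0 rose at 90 min, also adjusted over the list alone. At 45 min 0 rose and 0 fell in NAIL-WT by limma (0 and 1 adjusted over the list alone), and 3 rose and 1 fell in NAIL-ΔNFκB (4 and 1 adjusted over the list alone), and the list passed in neither line (adjusted p 0.685 and 0.423). The chaperone cofactor BAG3 fell by 0.42 and fell by 0.32 on the log2 scale, and DNAJB1 fell by 0.29 and fell by 0.33. Without NAIL-ΔNFκB 90 min replicate 1 neither passed in that line (-0.28 and -0.31), BAG3 did not pass there without NAIL-ΔNFκB 0 min replicate 2 (-0.27), and in NAIL-WT DNAJB1 did not pass without 90 min replicate 2 (-0.26) or when only the groups compared were fitted. The adjusted p of that list at 90 min was 0.000123 and 0.00505, and with an estimated correlation the adjusted p was 0.0924 and 0.163.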
